A study of Oryza sativa Japonica Group with 12 samples.

How the data were processed

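Per the labels, total RNA of anthers was amplified and labelled with Cy3 or Cy5, and RNA of a transgene and RNA of vector plants were hybridised together on Agilent rice arrays. Per the file headers, spots were read with Agilent Feature Extraction 10.5.1.1, and the deposited intensity columns are the mean brightness of each spot and the median brightness of its surroundings in each channel, not yet background-subtracted. Per the file headers, the deposited log10 ratio of red over green is background-subtracted with spatial detrending and dye-normalized. The authors' value table holds log2 ratios, by comparison with the scanner files: it was already turned to transgene over vector, with a slope of 0.998 to 0.999 against the scanner's own ratio on bright spots and array medians between -0.037 and 0.039. How the authors centred it is not given in the sources used here. It had 1 value outside any possible range, which was left out.

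Intensities were background-corrected by normexp with an offset of 50 and normalized within arrays by loess in limma 3.58.1 (R 4.3.3), with control spots given no weight. Ratios were turned by the dyes in the labels, spots of a probe were averaged, and spots with outlier flags (7 to 66 gene spots per array) were excluded. A probe was kept when it was well above background in at least 1 channel on at least 4 of 12 arrays. This left 36489 of 41889 gene probes and 25355 genes, with the probe of highest mean intensity standing for a gene; 7084 genes had several kept probes. Among named genes, probes of OsGAMYB, WDA1, TKPR1, MADS3, Os11g0115400 and Os06g0114000 differ in direction in at least 1 comparison. Probes of 1 direction differ in size for GA2ox1 (2.56 to 7.01 in OsGAMYB, 0.14 to 3.67 in SmGAMYB) and chalcone synthase C2 (2.53 to 7.32 in OsGAMYB, 2.83 to 7.89 in SmGAMYB, 1.03 to 4.93 in PpGAMYB2), and the values given are those of the brightest probe. Control spots and 510 microRNA probes were left out of these tests. Dye-swapped arrays were averaged, which gave 6 replicates, since they hold the same 2 RNA extracts. Median spot intensity was between 895 and 1447 in red and between 396 and 657 in green.

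Log2 ratios were fitted with limma lmFit and eBayes with a mean per transgene, all 6 replicates sharing an estimate of the spread with 3 residual degrees of freedom. Each mean was tested against 0 and against the others, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. Vector RNA was present only as the other channel. The 22 gene lists were tested with camera (preset correlation 0.01, and estimated) and fry, adjusted over the lists of a comparison. Where a gene was well above background on none of a group's arrays in 1 channel, a fold is given as at least the bright channel over the dim one, the dim channel set to the higher of its own signal and the lowest signal well above background, after Aquantile normalization between arrays.

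Tests, lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined. Chosen after seeing the data were the tests of candidate artifacts, the share restricted to replicates of the other number, the treatment of descriptions with the word uncharacterized as unknown in the rule for named genes, and the scoring of each list over the alternatives as the number of comparisons with vector in which camera called it. Genes named are OsGAMYB; the 8 highest and 8 lowest ratios per comparison with vector among described genes past the threshold and changed the same way on all 4 arrays; up to 3 called members of each list, or its 2 brightest if none was called; every member of the tapetum, sporopollenin and tapetum-secreted lists; and the 5 largest differences each way between transgenes. Not all are printed. Locus identifiers and descriptions come from the array files; symbols such as DPW come from lists of known rice genes written beforehand, and no genome coordinates were used here. The locus used for GID2 shares probes with another gene, so that member is uncertain.

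The fit was tested on simulated data in which 200 of 25355 genes were changed. The noise was drawn independently for each gene and replicate. The rates below therefore do not allow for variation shared between transgenes, such as that of shared vector RNA. For OsGAMYB with vector, 11.9% of genes changed 2-fold, 79.1% changed 4-fold and 92.4% changed 16-fold were recovered, with 2 false calls. For SmGAMYB the shares were 16.4%, 80.6% and 97.0% with 6 false calls, and for PpGAMYB2 10.4%, 79.1% and 95.5% with 7. Alternatives changed the background correction, normalization, source of the ratios, filters, probes per gene, dye orientation, model and replicates.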

Results

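Anthers of the rice cultivar Nipponbare were profiled at the microspore stage on 2-colour 44K arrays. All plants carried a mutation of GAMYB, a MYB transcription factor of the gibberellin pathway that anthers need to make pollen. The plants differed in the transgene they carried behind the promoter of the rice gene: the rice coding sequence OsGAMYB, its homolog SmGAMYB from the lycophyte Selaginella moellendorffii, its homolog PpGAMYB2 from the moss Physcomitrella patens, or an empty vector. Each array held RNA of a transgene on 1 channel and RNA of vector plants on the other. Each transgene had 2 biological replicates from separate RNA isolations, and each replicate was hybridised on 2 arrays with the dyes exchanged, which made 12 arrays in all. Between 80.2% and 85.9% of gene probes were well above background in the transgene channel, and between 77.5% and 87.6% in the vector channel. No gene probe was saturated, and the number of arrays limits the precision. The ratios of dye-swapped arrays correlated across genes with r between 0.94 and 0.97. Values below are log2 ratios of transgene over vector with the standard error of the limma fit (SE, n = 2 replicates), unless stated otherwise. This SE rests on a spread estimated from all 6 replicates together. It does not give the spread of the 2 replicates of the transgene named.

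The transcript of OsGAMYB itself (Os01g0812000, annotated as MYB8 on the array) did not pass the test with any transgene. Its log2 ratio was 0.00 ± 0.18 in OsGAMYB anthers, with 0.33 in replicate 1 and -0.32 in replicate 2 (adjusted p = 0.997). It was 0.15 ± 0.18 in SmGAMYB anthers (adjusted p = 0.617) and -0.34 ± 0.18 in PpGAMYB2 anthers (adjusted p = 0.430). All 5 probes of the gene were well above background in both channels on all 12 arrays, vector plants included, and their mean ratios differ in direction in OsGAMYB and SmGAMYB anthers. The probe names carry the tags CDS+3'UTR or 3'UTR, and the transgene carries the coding sequence. Whether the probes read the transcript of the rice transgene, or only the mutant's own, is not known here. The gene's level does not check the labels.

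The comparison of OsGAMYB with vector asks which genes respond when the rice factor is put back into the mutant. Genes of the tapetum, the anther layer that feeds the microspores, and of the pollen wall were among those that rose most. RTS (Os01g0929600), a tapetum gene needed for male fertility, rose by 8.30 ± 0.20, and the lipid transfer domain gene Os04g0415900 by 8.03 ± 0.19. OsC6 (Os11g0582500), a lipid transfer protein of the pollen wall, rose by 7.14 ± 0.69. Chalcone synthase C2 (Os11g0530600) rose by 7.32 ± 0.33, a gibberellin-regulated protein 2 precursor (Os05g0432200) by 7.83 ± 0.64, a GDSL lipase (Os04g0650200) by 7.004 ± 0.27 and cycloartenol synthase (Os08g0223900) by 6.90 ± 0.56. Among the genes that fell were 3 lipoxygenases, Os03g0738600 at -6.53 ± 0.62, Os12g0559200 at -5.77 ± 0.41 and Os12g0560200 at -3.74 ± 0.44. A beta-glucosidase aggregating factor (Os12g0247700) fell to -4.91 ± 0.17 and the class III chitinase Os01g0660200 to -3.86 ± 0.27.

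Of 14 measured genes of sporopollenin and pollen wall lipids, 6 rose in OsGAMYB anthers, none fell and 8 did not pass. Adjusted over the list alone, 9 rose. DPW, the reductase that makes fatty alcohols for the exine, rose by 4.92 ± 0.51, the exporter ABCG15 by 4.65 ± 0.75, and the fatty acid hydroxylases CYP704B2 and CYP703A3 by 4.31 ± 0.68 and 4.17 ± 0.57. The list's median was 4.00, and camera with a preset correlation called it (adjusted p = 5.2e-07; adjusted p = 0.625 with an estimated correlation). Of 6 tapetum-secreted and tapetal death proteins, RTS and the aspartic protease AP37 rose, the latter by 4.64 ± 0.39, and 4 did not pass. That list's median was 2.01 (camera, adjusted p = 0.020; adjusted p = 0.625 with an estimated correlation), with 0.98 in replicate 1 and 3.51 in replicate 2, and without replicate 2 the call ended; adjusted over the list alone 3 of its members rose. Of 9 tapetum regulators 2 rose and none fell, 4 and 2 adjusted over the list alone (median 0.78, camera adjusted p = 0.166, fry adjusted p = 0.018). PTC1, a PHD finger factor of tapetal development, rose by 3.11 ± 0.16 and EAT1, a bHLH factor of tapetal death, by 2.21 ± 0.32. TDR, a bHLH factor upstream of EAT1, stood at 1.45 ± 0.45 (adjusted p = 0.156) and MYB80 at 1.85 ± 0.88 (adjusted p = 0.301). Os03g0578900, annotated as a gibberellin MYB factor, rose by 4.10 ± 0.37.

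Of 13 measured genes of gibberellin synthesis and signalling, 5 rose and none fell in OsGAMYB anthers, 6 and none adjusted over the list alone. GA2ox1, an enzyme that inactivates gibberellin, rose by 7.01 ± 0.48 on its brighter probe, with 2.56 on the other. KAO rose by 3.39 ± 0.34 and GA3ox1, which makes active gibberellin, by 3.35 ± 0.48. The vector channel of GA3ox1 was well above background on 1 of 4 arrays. GA20ox1, named here after its values were seen, rose by 2.97 and was called with all 3 transgenes. The list's median was 0.75 (camera, adjusted p = 4.7e-04; adjusted p = 0.625 with an estimated correlation), with 1.35 in replicate 1 and 0.32 in replicate 2, and was 1.14 with the scanner's own ratio. Of 5 measured genes of pollen sugar supply and late pollen, the sugar transporter MST8 rose by 5.17 ± 0.32 and the cell wall invertase INV4 by 2.51 ± 0.33, with a list median of 2.51; adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.036; adjusted p = 0.625 with an estimated correlation). That call ended without OsGAMYB replicate 1, with Cy5 arrays alone and with the strict background filter.

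Among genes of meiosis and chromatin, medians were below 0 in OsGAMYB anthers. Of 8 meiosis genes PAIR3 fell, to -1.38 ± 0.22, none rose, and 2 fell adjusted over the list alone. The median was -0.97 (camera, adjusted p = 0.025; adjusted p = 0.625 with an estimated correlation), with -0.58 in replicate 1 and -1.51 in replicate 2, and without replicate 2 the call ended. Core histones had a median of -0.38 over 45 genes, with 1 that fell over all genes and adjusted over the list alone, the histone H2A gene Os12g0530000 at -1.03 ± 0.15 (adjusted p = 4.7e-04 for the list; adjusted p = 0.719 with an estimated correlation). Their median was 0.05 in replicate 1 and -0.998 in replicate 2. Photosynthesis genes, which also mark green tissue, had a median of 0.53 over 64 genes, with 1 that rose over all genes and 0 adjusted over the list alone (adjusted p = 0.013; adjusted p = 0.812 with an estimated correlation), but the median was -0.48 in replicate 1 and 1.36 in replicate 2. Among 154 cytochrome P450 genes 22 rose and 4 fell, 35 and 7 adjusted over the list alone. Among 75 genes of fatty acid and acyl metabolism 4 rose and 1 fell, 15 and 1 adjusted over the list alone. Camera called both lists upward (adjusted p = 0.036 and 0.043; adjusted p = 0.676 and 0.625 with an estimated correlation). Both calls ended without OsGAMYB replicate 1. The fatty acid call also ended with each of these: the replicate number as a block, median centring, no filter on dim probes, the mean of all probes, and Cy5 arrays alone.

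In total, 778 genes rose and 291 fell in OsGAMYB anthers among 25355 tested (limma with Benjamini-Hochberg adjustment), 862 of them by at least 2-fold. The scanner's own ratio gave 892 and 502. With the 2 OsGAMYB replicates fitted alone (1 residual degree of freedom) 0 genes passed with limma, 3406 at an unadjusted p under 0.05; 654 passed among genes well above background in both channels on all arrays, 3420 with all 12 arrays, the replicate as a random block and a dye term, 329 without OsGAMYB replicate 1, 308 without a SmGAMYB replicate and 218 without a PpGAMYB2 replicate. The fit of all 12 arrays, here and for the other transgenes, counts dye-swapped arrays of the same extracts toward its degrees of freedom. Its counts may therefore be too high. Vector RNA is present only as the other channel, so the spread between vector samples enters only through the ratios of the replicates. If vector samples were shared between transgenes, the 3 residual degrees of freedom are not independent, which the fit does not allow for.

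**Figure D1:**
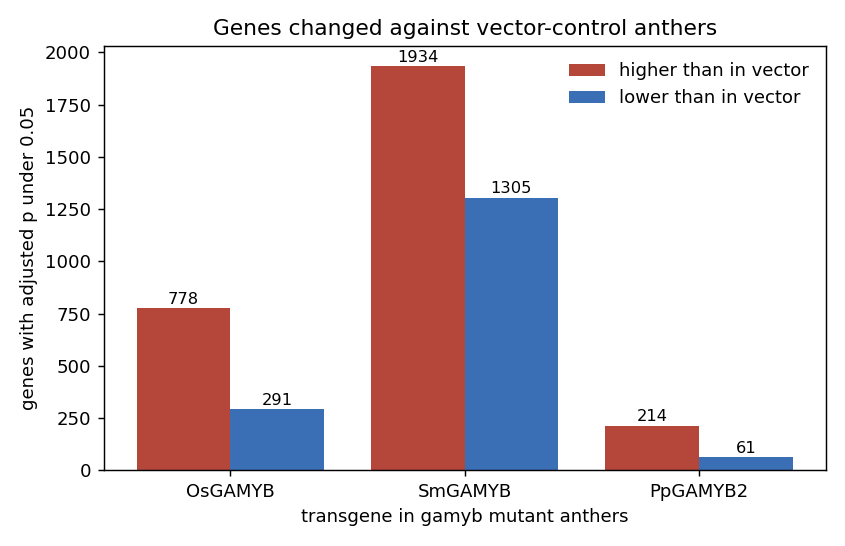
Bars give the number of genes with an adjusted p under 0.05 (vertical axis) in anthers of each transgene against vector, higher in red and lower in blue. SmGAMYB anthers have 1934 higher and 1305 lower genes, OsGAMYB 778 and 291, and PpGAMYB2 214 and 61.

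The comparison of SmGAMYB with vector asks whether the lycophyte factor can act in the rice mutant. OsC6 rose by 8.49 ± 0.69, RTS by 7.64 ± 0.20, chalcone synthase C2 by 7.89 ± 0.33, the GDSL lipase Os04g0650200 by 7.63 ± 0.27 and the lipid transfer domain gene Os04g0415900 by 7.06 ± 0.19. A purple acid phosphatase (Os12g0637000) rose by 7.22 ± 0.61, and the P450 genes Os01g0183500 and Os04g0570600 by 7.58 ± 0.89 and 7.13 ± 0.68. The lipoxygenases Os03g0738600 and Os12g0559200 fell to -6.41 ± 0.62 and -5.78 ± 0.41, the chitinase Os01g0660200 to -5.05 ± 0.27 and a chalcone synthase, Os07g0526400, to -6.05 ± 1.22. Camera did not call the lists of lipid transfer, P450 and chalcone synthase genes in SmGAMYB anthers. Of 57 lipid transfer proteins 5 rose and 7 fell, 5 and 9 adjusted over the list alone (median -0.06, camera adjusted p = 0.787). Of 154 cytochrome P450 genes 24 rose and 12 fell, 29 and 24 adjusted over the list alone (median -0.09, camera adjusted p = 0.960). Of 16 chalcone and stilbene synthases 3 rose and 2 fell, 3 and 3 adjusted over the list alone (median 0.08, camera adjusted p = 0.888), and fry called that list (adjusted p = 0.031).

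Of the 14 genes of sporopollenin and pollen wall lipids, 7 rose in SmGAMYB anthers and none fell, 8 and none adjusted over the list alone. DPW rose by 5.02 ± 0.51, ABCG15 by 4.87 ± 0.75, the polyketide synthase PKS1 by 4.50 ± 0.88 and CYP704B2 by 4.35 ± 0.68. The median was 3.44 (camera, adjusted p = 1.6e-04; adjusted p = 0.936 with an estimated correlation). The tapetum-secreted proteins RTS, AP25 and AP37 rose, AP25 by 4.54 ± 0.71 and AP37 by 4.40 ± 0.39, with a list median of 2.79 and 3 that rose adjusted over the list alone (camera adjusted p = 0.041; adjusted p = 0.936 with an estimated correlation). Among tapetum regulators PTC1 rose by 2.49 ± 0.16 and EAT1 by 2.35 ± 0.32, while TIP2, a bHLH factor that acts before EAT1, fell to -1.58 ± 0.29 and the receptor kinase gene MSP1 to -0.51 ± 0.11. Adjusted over the list alone the counts were again 2 and 2, and the list's median of 0.58 did not pass (camera adjusted p = 0.534). Of 13 gibberellin genes 3 rose, also adjusted over the list alone: GA2ox1 by 3.67 ± 0.48 on its brighter probe, with 0.14 on the other, GA20ox1 by 2.71 ± 0.11 and GA20ox2 by 0.92 ± 0.15; the list did not pass (median 0.28, adjusted p = 0.082). The vector channel of GA2ox1 was well above background on 1 of 4 arrays. MST8 rose by 4.04 ± 0.32, and CSA, the MYB factor that controls anther sugar supply, by 3.72 ± 0.49, while UGP1 of the same list fell to -0.79 ± 0.12. Over the 5 measured genes of pollen sugar supply and late pollen 2 rose and 1 fell, also adjusted over the list alone, and the list did not pass (median 0.25, camera adjusted p = 0.534).

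Of the 8 meiosis genes in SmGAMYB anthers 3 fell and 1 rose. ZEP1, a synaptonemal complex gene, fell to -2.80 ± 0.55, DMC1B to -2.38 ± 0.31 and PAIR3 to -2.05 ± 0.22, while the recombinase gene DMC1A, named after its values were seen, rose by 1.38 ± 0.22. Adjusted over the list alone 4 fell and 1 rose. The list's median was -1.48 (camera, adjusted p = 0.041; adjusted p = 0.936 with an estimated correlation). Of 45 core histone genes 11 fell and none rose, 19 and none adjusted over the list alone, with a median of -0.80 (adjusted p = 4.4e-05; adjusted p = 0.936 with an estimated correlation). Of 14 starch synthesis genes 3 fell, also adjusted over the list alone, with a median of -0.35 (adjusted p = 0.041; adjusted p = 0.936 with an estimated correlation); without SmGAMYB replicate 1 that call ended. Photosynthesis genes had a median of 0.70, with 8 that rose and 1 that fell, 9 and 1 adjusted over the list alone (adjusted p = 0.013; adjusted p = 0.936 with an estimated correlation), but their median was -0.02 in replicate 1 and 1.26 in replicate 2.

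In total, 1934 genes rose and 1305 fell in SmGAMYB anthers, 1913 of them by at least 2-fold. The scanner's own ratio gave 1712 and 1449. With the SmGAMYB replicates fitted alone 1061 genes passed, 6210 with all 12 arrays, the replicate as a random block and a dye term, and 527 without a PpGAMYB2 replicate. With either SmGAMYB replicate left out 0 passed with limma, where the lone replicate is assumed to vary like those of the other groups.

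**Figure D2:**
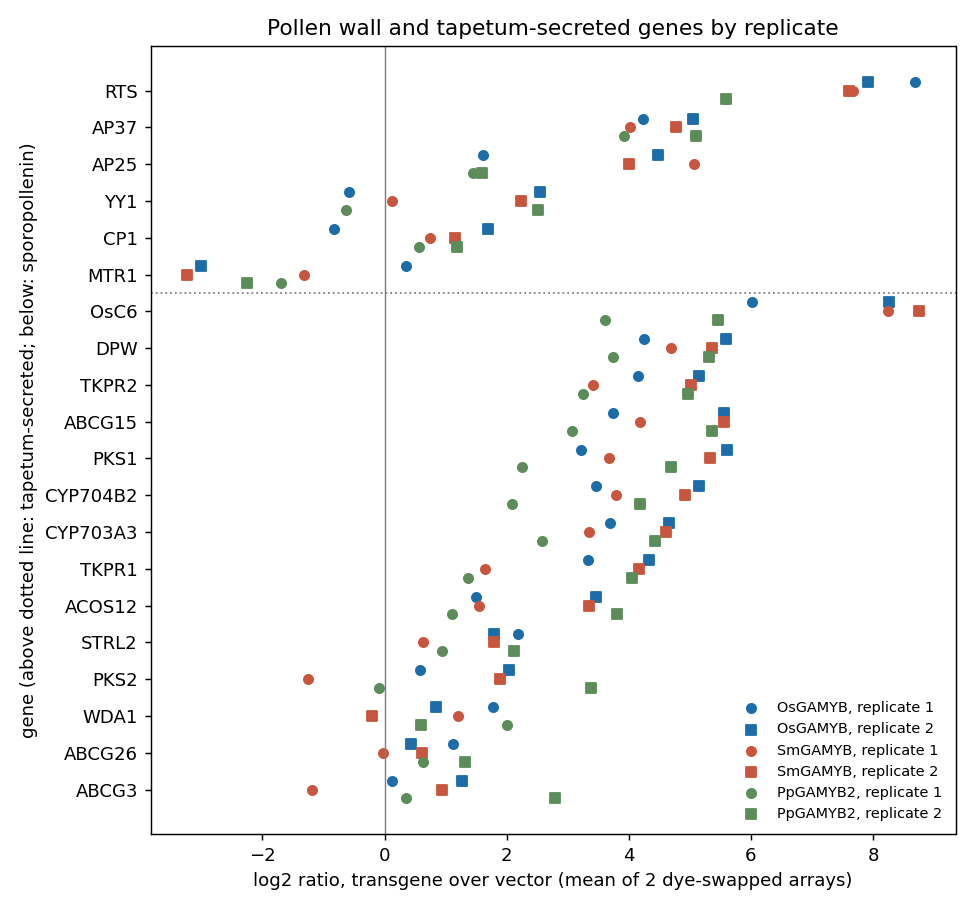
Points give the log2 ratio of transgene over vector (horizontal axis) for 6 tapetum-secreted genes above the dotted line and 14 sporopollenin genes below it, with colour for the transgene and shape for the replicate, each point the mean of 2 dye-swapped arrays. DPW lies between 3.74 and 5.59 in all 6 replicates.

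The comparison of PpGAMYB2 with vector asks the same of the moss factor. The lipid transfer domain gene Os04g0415900 rose by 6.11 ± 0.19, RTS by 5.59 ± 0.20, the subtilisin-like protease gene Os02g0198700 by 5.52 ± 0.28, the GDSL lipase Os04g0650200 by 5.46 ± 0.27 and chalcone synthase C2 by 4.93 ± 0.33. An aquaporin family gene (Os01g0112400) rose by 5.71 ± 0.21 and the LOB domain gene Os01g0772100 by 5.28 ± 0.47. Among the genes that fell were a class IV small heat shock protein (Os04g0445100), to -4.87 ± 0.40, a small heat stress protein of class CIII (Os02g0782500), to -3.77 ± 0.28 and the 101 kDa heat shock protein (Os05g0519700), to -3.09 ± 0.29, all 3 of which also fell in OsGAMYB and SmGAMYB anthers. The heat shock list was drawn by a keyword that leaves out the class CIII gene. Of its 108 measured genes 2 fell and none rose, also adjusted over the list alone, and the list did not pass (median -0.06, adjusted p = 0.309).

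Of the 14 sporopollenin genes in PpGAMYB2 anthers only DPW passed over all genes, at 4.52 ± 0.51, while 10 rose adjusted over the list alone. OsC6 stood at 4.53 ± 0.69 (adjusted p = 0.073) and ABCG15 at 4.21 ± 0.75 (adjusted p = 0.096). The list's median was 2.92 (camera, adjusted p = 7.3e-09; adjusted p = 0.489 with an estimated correlation). RTS and AP37 rose among tapetum-secreted proteins, AP37 by 4.51 ± 0.39, also adjusted over the list alone, with a median of 1.24 (camera adjusted p = 0.010; adjusted p = 0.489 with an estimated correlation), 1.01 in replicate 1 and 2.06 in replicate 2. PTC1 rose by 2.30 ± 0.16, and EAT1 stood at 1.04 ± 0.32 (adjusted p = 0.218). Of the gibberellin genes GA20ox1 rose by 2.26 ± 0.11, and 2 rose adjusted over the list alone (list median 0.25, adjusted p = 0.062). MST8 was at least 8.22-fold higher, since its vector channel was not well above background on any array of the group (adjusted p = 0.041). Its list of 5 genes did not pass (median 0.23, camera adjusted p = 0.494), with 1 that rose, and 1 that rose and 1 that fell adjusted over the list alone. Of 57 lipid transfer proteins 5 rose and 1 fell, 14 and 2 adjusted over the list alone, with a median of 0.41 (camera, adjusted p = 8.9e-04; adjusted p = 0.489 with an estimated correlation), 0.43 in replicate 1 and 0.66 in replicate 2. None of the 8 meiosis genes passed over all genes, 5 fell adjusted over the list alone, and the median was -1.16 (adjusted p = 7.3e-04; adjusted p = 0.489 with an estimated correlation). Core histones had a median of -0.67 with 1 that fell, also adjusted over the list alone (adjusted p = 3.7e-09; adjusted p = 0.506 with an estimated correlation). Photosynthesis genes had a median of 0.40, with none that passed over all genes and 2 that rose adjusted over the list alone (adjusted p = 0.0078; adjusted p = 0.728 with an estimated correlation), with -0.35 in replicate 1 and 1.04 in replicate 2.

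In total, 214 genes rose and 61 fell in PpGAMYB2 anthers, 265 of them by at least 2-fold. The scanner's own ratio gave 289 and 117. With the PpGAMYB2 replicates fitted alone 0 genes passed with limma, 4239 at an unadjusted p under 0.05, and with either PpGAMYB2 replicate left out 0 passed. The count was 137 among genes well above background in both channels on all arrays, 172 with a trended and robust prior, 1959 with all 12 arrays, the replicate as a random block and a dye term, and 14 without a SmGAMYB replicate.

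Set against vector, camera did not call proteases (145 genes), pollen cell wall enzymes and allergens (80), pathogenesis-related proteins (94) or GDSL lipases (75). Nor did it call chalcone and stilbene synthases (16), MYB factors (102) or ribosomal proteins (300). Medians of these lists lay between -0.19 and 0.14 in the 3 comparisons. In OsGAMYB anthers 9, 8, 6, 7, 3, 6 and 0 of their genes rose, in that order. Those that fell numbered 2, 6, 8, 2, 0, 2 and 0, where 778 of all 25355 genes rose and 291 fell. A median near 0 therefore does not mean that no member changed. ABC transporters (76 genes), bHLH factors (96) and starch synthesis were called in PpGAMYB2 anthers, with medians of 0.08, 0.09 and -0.32 (adjusted p = 0.034, 0.049 and 0.048; adjusted p = 0.489, 0.728 and 0.506 with an estimated correlation). Each of these 3 calls ended without PpGAMYB2 replicate 1. Cytochrome P450 genes had a median of 0.10 there (adjusted p = 0.0022; adjusted p = 0.506 with an estimated correlation), 0.18 in replicate 1 and 0.04 in replicate 2. Over the 22 lists, camera with a preset correlation called 9 lists in OsGAMYB, 6 in SmGAMYB and 10 in PpGAMYB2 anthers, and with an estimated correlation 0 in each. The rotation test fry, which asks whether a list's genes move 1 way on balance, called 8, 2 and 2 lists. It called tapetum-secreted proteins in each comparison with vector (adjusted p = 0.0072, 0.0080 and 0.014). Sporopollenin genes passed fry in OsGAMYB (adjusted p = 0.042) but not in SmGAMYB (0.063) or PpGAMYB2 (0.073). In OsGAMYB fry also called tapetum regulators, lipid transfer proteins and chalcone and stilbene synthases, which camera did not. Meiosis, core histone and photosynthesis lists did not pass fry in any comparison with vector.

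**Figure D3:**
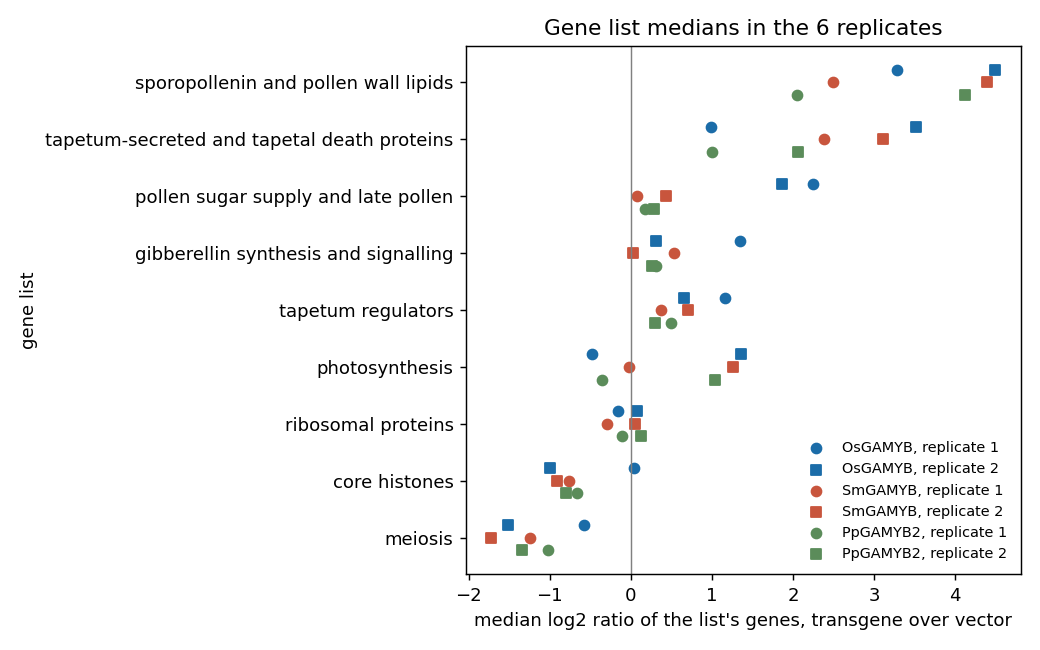
Points give the median log2 ratio of transgene over vector (horizontal axis) of 9 gene lists in each of the 6 replicates, with colour for the transgene and shape for the replicate. Sporopollenin medians lie between 2.05 and 4.49, meiosis medians between -1.72 and -0.58, and photosynthesis medians are below 0 in replicate 1 and above 1 in replicate 2 of every transgene.

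The transgenes were then set against each other through the vector channel. A pair of genes annotated as homeodomain-like, Os01g0549300 and Os08g0178900, was higher with PpGAMYB2 than with OsGAMYB (adjusted p = 0.029 for both) and than with SmGAMYB (adjusted p = 0.027 for both). Their vector channel was not well above background on any array, so the size of these differences in ratios is not measured. In PpGAMYB2 anthers they were at least 21.2-fold and 15.5-fold higher than in vector. Os08g0178900 was not well above background with OsGAMYB or SmGAMYB on any array, and its transgene channel was at least 17.7-fold and at least 16.8-fold brighter with PpGAMYB2. Os01g0549300 was well above background on 2 of 4 OsGAMYB arrays and on all 4 SmGAMYB arrays, and its transgene channel was at least 23.3-fold brighter with PpGAMYB2 than with OsGAMYB and 19.0-fold brighter than with SmGAMYB. Whether the probes of this pair also bind the transcript of the moss transgene was not checked here. The conserved hypothetical genes Os04g0115200 and Os07g0442800, named after their values were seen, were higher with PpGAMYB2 than with SmGAMYB (adjusted p = 0.027 for both). Their transgene channel, well above background on all arrays, was 94.4-fold and 107-fold brighter with PpGAMYB2 than with SmGAMYB. Their vector channel was well above background on all 4 PpGAMYB2 arrays, on 1 and 2 of the OsGAMYB arrays and on none of the SmGAMYB arrays, so the SmGAMYB ratios against it are not measured. Against vector, Os04g0115200 stood at 5.47 and 5.39 in OsGAMYB replicates 1 and 2 and at 6.14 and 6.41 in PpGAMYB2 replicates, and Os07g0442800 at 5.57 and 5.43 and at 6.19 and 6.497. Neither gene passed between SmGAMYB and OsGAMYB (adjusted p = 0.061 for both) or between PpGAMYB2 and OsGAMYB (adjusted p = 0.478 and 0.528). The non-coding transcript Os11g0139700 was lower with PpGAMYB2 than with SmGAMYB, at -2.83 (adjusted p = 0.045), with ratios to vector of -0.04 and 0.02 in OsGAMYB, 1.47 and 1.47 in SmGAMYB and -1.41 and -1.29 in PpGAMYB2 replicates. The calls between transgenes ended (0 genes) when any replicate was left out, with the scanner's own ratio, with Cy5 arrays alone, with the strict background filter and with only the compared groups fitted. With the replicate number as a block, more genes passed in each comparison of transgenes, most of all between PpGAMYB2 and SmGAMYB. If vector RNA of a number was shared between slides, a fit without that block counts its variation as spread. Few calls without the block thus do not show that the transgenes act alike. No gene passed between SmGAMYB and OsGAMYB with limma without that block, against 1825 at an unadjusted p under 0.05 where chance gives 1268. With all 12 arrays, the replicate as a random block and a dye term, 202 genes passed there, 215 between PpGAMYB2 and OsGAMYB and 1289 between PpGAMYB2 and SmGAMYB. The random-block fit counts dye-swapped arrays of the same extracts, correlated at 0.956, toward its degrees of freedom, so its counts may be too high. The gibberellin list had a lower median with SmGAMYB than with OsGAMYB, at -0.26 (camera, adjusted p = 0.0065; adjusted p = 0.730 with an estimated correlation), and with PpGAMYB2, at -0.62 (camera adjusted p = 3.7e-04; adjusted p = 0.606 with an estimated correlation). The first call ended without SmGAMYB replicate 2, and the second median was -0.27 without OsGAMYB replicate 1. Sporopollenin genes did not pass in any of the 3 comparisons of transgenes, with medians of -0.32, -0.45 and -0.15. Each transgene lay on a slide of its own, so slide and transgene cannot be told apart here; the OsGAMYB and SmGAMYB slides were scanned on the same day and the PpGAMYB2 slide on another.

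Calls were shared between transgenes. OsGAMYB and SmGAMYB anthers shared 605 higher and 241 lower genes, where independent lists would share 59.3 and 15.0. OsGAMYB and PpGAMYB2 shared 165 and 45, against 6.57 and 0.70, and SmGAMYB and PpGAMYB2 shared 157 and 41, against 16.3 and 3.14. The 3 comparisons use the same estimate of the spread for a gene, so their lists are not independent by construction. The expected numbers do not allow for that. Higher in all 3 were 145 genes, and lower in all 3 were 37. In 100 simulations of unchanged groups sharing vector RNA a group had at most 1 call, so the simulated number of shared genes, at most 1, gives chance with no effect and does not measure what shared RNA adds to real calls. Without a SmGAMYB replicate 0 genes were shared in the pairs with SmGAMYB, and without a PpGAMYB2 replicate 0 in the pairs with PpGAMYB2, as no gene of that transgene was then called. OsGAMYB and SmGAMYB shared 288 genes without OsGAMYB replicate 1, 455 without OsGAMYB replicate 2 and 180 without a PpGAMYB2 replicate, and OsGAMYB and PpGAMYB2 shared 137 without OsGAMYB replicate 1 and 11 without a SmGAMYB replicate. Across genes the log2 ratios correlated with r of 0.81, 0.74 and 0.62 for the 3 pairs in that order, and the simulation gave 0.72 for each. That simulated r returns the simulation's own setting, a shared fraction of 0.725 estimated from the replicate differences of these data. It is therefore no separate benchmark for the observed r. Covariances were 0.55, 0.34 and 0.33 against a simulated 0.064. Part of the excess may come from the shared controls. Between replicates of different number, r was 0.50 and 0.63 for OsGAMYB and SmGAMYB, 0.42 and 0.48 for OsGAMYB and PpGAMYB2, and 0.40 and 0.36 for SmGAMYB and PpGAMYB2. Between the 2 replicates of a transgene it was 0.56 for OsGAMYB, 0.75 for SmGAMYB and 0.61 for PpGAMYB2; genes are not independent replicates.

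The share of the OsGAMYB response was measured on genes picked in 1 OsGAMYB replicate and signed by it, and set against the held-out OsGAMYB replicate. The 3113 genes that differed at least 2-fold in OsGAMYB replicate 1 had a median of 0.88 in OsGAMYB replicate 2. Their medians were 1.09 and 0.82 in SmGAMYB replicates 1 and 2, and 0.67 and 0.46 in PpGAMYB2 replicates 1 and 2. The 3760 genes picked in OsGAMYB replicate 2 had a median of 0.67 in OsGAMYB replicate 1. Their medians were 0.94 and 1.60 in SmGAMYB replicates 1 and 2, and 0.45 and 1.05 in PpGAMYB2 replicates 1 and 2. Averaged over both replicates of a transgene, the SmGAMYB medians were 108.3% and 189.5% of the held-out OsGAMYB median, and the PpGAMYB2 medians 64.3% and 112.2%. For genes picked in replicate 1 the shares were 102.8% for higher and 121.8% for lower genes with SmGAMYB, and 67.4% and 59.1% with PpGAMYB2. For genes picked in replicate 2 they were 140.0% for higher and 246.5% for lower genes with SmGAMYB, and 78.4% and 150.2% with PpGAMYB2. Restricted to the replicate whose number differs from the picking one, the shares over both directions were 93.5% and 140.3% with SmGAMYB, and 52.6% and 67.6% with PpGAMYB2. So restricted, genes picked in replicate 1 had 84.7% for higher and 120.2% for lower genes with SmGAMYB, and 53.7% and 52.1% with PpGAMYB2. Genes picked in replicate 2 had 123.0% for higher and 151.8% for lower genes with SmGAMYB, and 56.0% and 71.9% with PpGAMYB2. This restriction was chosen after seeing that replicates of the same number resemble each other across transgenes. If vector RNA of a number was shared, a same-numbered replicate meets the picking replicate's vector RNA again. The held-out OsGAMYB replicate does not, which would raise the unrestricted shares, so these do not measure the strength of a transgene against OsGAMYB. No test was made of these shares.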

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

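The tests of the meiosis list and of the dyes were chosen only after their values were seen; the tests of the vector channel, array position and green tissue were written before their results but after the patterns were seen. Differences between transgenes are results of the tests planned beforehand.

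Genes and lists that differ between transgenes were picked out by the test of the difference itself. The homeodomain-like gene Os01g0549300 was higher with PpGAMYB2 by 4.33 than with OsGAMYB and by 4.01 than with SmGAMYB, and Os08g0178900 by 4.05 and 3.78. These are differences of fitted ratios with the vector channel at background on every array, so their size is not measured. Os04g0115200 and Os07g0442800 were higher with PpGAMYB2 than with SmGAMYB by 5.37 and 5.35, and Os11g0139700 was at -2.83. Against vector Os04g0115200 and Os07g0442800 lay between 5.39 and 5.57 in the OsGAMYB replicates and between 6.14 and 6.497 in PpGAMYB2, and their vector channel was well above background on no SmGAMYB array, so the size of their differences from SmGAMYB is not measured either. Neither passed between SmGAMYB and OsGAMYB (adjusted p = 0.061). Relative to OsGAMYB, list medians were lower with SmGAMYB for gibberellin genes (-0.26), lipid transfer proteins (-0.45), cytochrome P450 genes (-0.23) and core histones (-0.29), and with PpGAMYB2 for gibberellin genes (-0.62). For pollen sugar supply and late pollen genes they were -0.47 with SmGAMYB and -1.98 with PpGAMYB2, where none of the 5 measured genes passed. With a replicate left out, the histone median with SmGAMYB ranged from -0.67 to 0.088. The sugar supply and late pollen median with SmGAMYB changed sign with the strict background filter. Relative to SmGAMYB, PpGAMYB2 had higher medians of lipid transfer proteins (0.26) and cytochrome P450 genes (0.30). These list differences rest on camera with a preset correlation, and with an estimated correlation the lowest adjusted p in each comparison was 0.730, 0.606 and 0.966.

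An array lay far from the other 3 of its group in 3 of 314 groups, where chance gives about 1 in 20 for independent values. These arrays are not independent, being 2 replicates hybridised with both dye orientations, so that rate does not apply here. For Os12g0247700 in OsGAMYB it was -4.12 against -5.26 to -5.12, for Os04g0415900 in SmGAMYB 7.17 against 7.01 to 7.03, and for the ABC transporter list in OsGAMYB 0.013 against 0.064 to 0.072.

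The microRNA probes, outside the gene tests, held signal that differed from vector: of 188 measured probes 10 passed in OsGAMYB, 48 in SmGAMYB and 7 in PpGAMYB2. Both measured probes of miR169b were higher in each, by 4.25 and 3.65 in OsGAMYB, and both of miR528 lower, at -2.13 and -1.89. No probe of the miR159 family, known to target GAMYB transcripts, passed. The measured miR159 probes, like those named for miR169b and miR528, are labelled 5'seq or 3'seq and none of them mature. Their values thus do not give the level of the mature microRNAs.

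Ratios of the same replicate number resembled each other across transgenes: r across genes was 0.60 to 0.85, against 0.56, 0.75 and 0.61 between the replicates of OsGAMYB, SmGAMYB and PpGAMYB2. If vector RNA of each number was shared between slides, the vector channel's difference between replicates should correlate between slides, and it did, with a mean r across genes of 0.975. The transgene channel's difference had a mean r of 0.083, and the gap of 0.892 argues against an effect of array position alike in both channels. Such an effect would cancel in the ratios, and a position effect on the vector channel alone was not tested. A candidate explanation of the vector channel's correlation is that 2 vector extracts served all 12 arrays. The comparisons with vector would then rest on 2 control samples.

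Photosynthesis genes had medians below 0 in replicate 1 and above 1 in replicate 2 of each transgene. The list's difference between replicates was larger in the vector channel than in the transgene channel on 3 of 3 slides (1.12, 1.21 and 1.14, against -0.88, 0.0047 and 8.3e-04), which is consistent with more green tissue RNA in the vector sample of replicate 1. If the same 2 vector extracts served all slides, the 3 vector differences are 1 difference measured 3 times, so the slides do not count as 3 separate tests. Within each dye orientation the list was higher in replicate 2 than in replicate 1 by 1.22 to 1.91, and orientations of a replicate differed by at most 0.30, which argues against dye bias as the cause. An earlier test of the dyes, by the sign of the median in both orientations, held in 5 of 6 replicates and did not decide, as SmGAMYB replicate 1 lay near 0. A difference in plastid activity of the vector anthers was not tested.

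The median of the meiosis list was below 0 in every comparison with vector. The highest of the 6 replicate medians was -0.58, which argues against a single vector sample as the only source. An earlier stage of both vector samples, and an effect of the transgenes on the passage through meiosis, stay open and were not tested.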

How the results depend on the processing

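The share restricted to replicates of the other number, and the scoring of each list as the number of comparisons with vector in which camera called it, were chosen after seeing the data. The cause of the changes below was not tested unless the setting itself (fewer genes, replicates or degrees of freedom) gives it. The OsGAMYB transcript kept its side of the threshold in all 60 checks, over 3 comparisons. Named genes had 4300 of 5213 alternatives with the same call, 847 that lost it, 66 that gained it and 0 that reversed. List medians had 14 reversals in 2376. The mean share was 148.9% for SmGAMYB and 88.2% for PpGAMYB2 over every replicate, and 116.9% and 60.1% restricted to the other number. The share of higher calls moved by under 10 points and the median of all genes by under 0.1 with any scaling. Dim channels limit folds where vector is near background. Lists were not run with the random block or the trended prior, nor the share with a block, prior or left-out replicate.

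Counts of changed genes are given for OsGAMYB, SmGAMYB and PpGAMYB2 against vector, then SmGAMYB against OsGAMYB, PpGAMYB2 against OsGAMYB and PpGAMYB2 against SmGAMYB. They were 1069, 3239, 275, 0, 2 and 5. With the replicate number as a block they were 7207, 11268, 4155, 7, 4 and 3119, and the calls shared by the pairs were 5481, 2800 and 2681. If vector RNA of a number was shared, this block takes the variation between the vector samples out of the error. The blocked counts against vector, and the calls shared by the pairs, may then be too high. Replicates share only a number in the labels, and with 2 numbers the correlations of same-numbered replicates across transgenes (0.60 to 0.85) do not show a pairing by design. The vector channel's own correlation between slides is a hint from the data that vector RNA of a number was shared, not from the labels. With the block camera called 3 lists in SmGAMYB, and the number of comparisons calling a list fell to 0 for late pollen, fatty acid, ABC transporter and bHLH genes, to 1 for P450 and starch genes, and was 1 for heat shock proteins. With a random block and a dye term the counts were 3420, 6210, 1959, 202, 215 and 1289, with 2487, 1231 and 1222 shared. That fit counts dye-swapped arrays of the same extracts toward its degrees of freedom, so these counts may be too high.

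With only the compared groups fitted, counts were 0, 1061, 0, 0, 0 and 0, with 0 shared in each pair; tapetum regulators and pathogenesis-related proteins were called in 1 comparison and bHLH factors in 0. Among genes well above background on all arrays, OsGAMYB had 654, PpGAMYB2 137 and the differences of PpGAMYB2 from OsGAMYB and SmGAMYB 0, with 557, 118 and 108 shared, fewer genes being tested. There camera called 6 and 5 lists between PpGAMYB2 and the others, proteases and pollen wall enzymes in 1 comparison, P450 in 1 and late pollen in 0, and the late pollen median between SmGAMYB and OsGAMYB reversed to 0.23. With a trended and robust prior PpGAMYB2 had 172 genes, SmGAMYB against OsGAMYB 2, and SmGAMYB and PpGAMYB2 shared 131. At 2-fold or more SmGAMYB had 1913.

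With the scanner's own ratio the differences of PpGAMYB2 from OsGAMYB and SmGAMYB had 0 genes, the overlaps with PpGAMYB2 were 317 and 303, camera called 4 lists between PpGAMYB2 and OsGAMYB, gibberellin genes in 3 comparisons and starch in 0. With the authors' value table SmGAMYB against OsGAMYB had 1 gene, PpGAMYB2 against OsGAMYB 4 lists, gibberellin was called in 3, starch in 1 and bHLH in 0 comparisons. With median centring SmGAMYB against OsGAMYB had 3 genes, PpGAMYB2 against SmGAMYB 4 lists, ribosomal proteins were called in 2, starch in 1, fatty acid and bHLH genes in 0. Without background subtraction PpGAMYB2 against SmGAMYB had 4 lists, starch 1 and bHLH 0. Without a filter PpGAMYB2 against SmGAMYB had 0 lists, P450 1, fatty acid and ABC transporter genes 0. With the mean of all probes fatty acid genes had 0 and pathogenesis-related proteins 1. With Cy5 arrays alone the differences of PpGAMYB2 had 0 genes, and late pollen, fatty acid, ABC transporter and starch lists 0. With Cy3 arrays alone SmGAMYB against OsGAMYB had 1 gene, gibberellin 2, pathogenesis-related proteins 1 and bHLH 0.

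With each replicate left out in turn, counts ranged from 218 to 737 for OsGAMYB, 0 to 3493 for SmGAMYB and 0 to 225 for PpGAMYB2, and were 0 for both differences of PpGAMYB2. Shared calls ranged from 0 to 455, 0 to 141 and 0 to 175. Lists called ranged from 5 to 10, 3 to 11 and 2 to 8 in the 3 comparisons of transgenes. Comparisons calling a list ranged from 1 to 2 for gibberellin, P450 and starch, 0 to 2 for pathogenesis-related proteins and 0 to 1 for late pollen, GDSL, fatty acid, ABC transporter, protease, pollen wall enzyme, ribosomal, heat shock and bHLH lists. Medians that reversed ranged as follows. Against vector, photosynthesis genes ranged from -0.48 to 1.36 in OsGAMYB, -0.018 to 1.26 in SmGAMYB and -0.35 to 1.04 in PpGAMYB2, below 0 without replicate 2 of each. Histones in OsGAMYB ranged from -0.998 to 0.045, above 0 without replicate 2. In PpGAMYB2 ribosomal genes ranged from -0.11 to 0.13 and bHLH genes from -0.0084 to 0.26. Between SmGAMYB and OsGAMYB photosynthesis ranged from -0.88 to 0.96, ribosomal genes from -0.24 to 0.11, histones from -0.67 to 0.088 and bHLH genes from -0.19 to 0.19. Between PpGAMYB2 and OsGAMYB photosynthesis ranged from -1.15 to 0.81, with 0.38 without PpGAMYB2 replicate 1, and histones from -0.74 to 0.18.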

Other observations

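In SmGAMYB anthers 1934 of all 25355 genes rose and 1305 fell, and some lists that camera did not call held members of both kinds. Of 96 bHLH factors 17 rose and 4 fell (20 and 7 adjusted over the list alone), of 102 MYB factors 11 rose and 9 fell (13 and 13), and of 300 ribosomal protein genes 21 rose and 6 fell (15 and 4), with medians of 0.03, 0.11 and -0.12. Of 94 pathogenesis-related genes 9 rose and 15 fell in SmGAMYB anthers, against 6 and 8 in OsGAMYB anthers and 1 and 0 in PpGAMYB2 anthers. Adjusted over the list alone these counts were 12 and 25, 10 and 13, and 8 and 4, and the list did not pass between any pair of transgenes. The gibberellin MYB factor gene Os03g0578900 rose by 4.10 ± 0.37 in OsGAMYB, 4.89 ± 0.37 in SmGAMYB and 3.91 ± 0.37 in PpGAMYB2 anthers (limma, SE, n = 2 replicates).

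Genes at background in vector give lower bounds only. A heat shock protein 70 gene (Os11g0187600) was at least 8.23-fold higher in OsGAMYB anthers and at least 18.4-fold higher in SmGAMYB anthers, and a beta-expansin gene (Os10g0548600) at least 6.86-fold higher in OsGAMYB anthers. Shared calls in opposite directions were 17 between SmGAMYB and PpGAMYB2, 6 between OsGAMYB and SmGAMYB and 0 between OsGAMYB and PpGAMYB2.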
